A study of Homo sapiens with 6 samples.

How the data were processed

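RNA was measured in RPE-1 cells, a human retinal pigment epithelial line immortalised with telomerase, in 6 conditions. Per the labels' protocols, cells were arrested at the start of S phase by 24 h in 2 mM thymidine and released by 3 washes. From 1 h after the wash they received the solvent DMSO or the ATR inhibitor AZ20 at 2 µM. They were collected at 4 h of release (4h_DMSO and 4h_ATRi) or at 6 h of release (6h_DMSO and 6h_ATRi). Arrested cells that were not released and asynchronously cycling cells were the other conditions. Total RNA was isolated with Trizol and sequenced after preparation with a KAPA Stranded mRNA-Seq kit, per the labels' protocols.

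The authors deposited a table of read counts per gene, with whole numbers that were not normalised. The columns carry the letters A, B and C, which were taken as the 3 independent experiments of the series' design text. Alignment with TopHat to GRCh37, counting with HTSeq and testing with DESeq2 are named in the submitters' processing notes. Tool versions, the annotation release and the strand setting of the counting are not given in the sources used here. A second table that the authors deposited holds log2 fold changes for 6 comparisons. The same deposited table holds an adjusted p-value for each gene and comparison. The direction of each of its comparisons was checked against the counts.

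The count table has 60252 gene IDs and 17 columns. Experiment C of 6h_ATRi is not analysed here, so that condition has 2 libraries and each other condition has 3. Every entry carries a gene ID, and 55528 IDs were matched to symbols in the name table. No GRCh37 annotation was used. The GENCODE annotation of GRCh38 served only for names and for which genes overlap on opposite strands, and no coordinates were taken from it. Totals per library ran from 1758747 to 2357561 counts, with a mean of 2032000 ± 179400 (SD, n = 17). Levels are given as CPM, counts scaled to a common library total. At this depth a gene at 1 CPM has about 2 counts in a library, so fold changes of low genes are imprecise. The counts carry no molecular identifiers.

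Features were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13510. Of these, 7086 have an exon overlapped by an exon on the opposite strand, 6208 have none and 216 are not in the annotation. Because the counts lie mostly on the opposite strand of abundant genes, a count on an overlapped feature can belong to the gene named or to its partner. Of 1001 pairs of a coding gene and an antisense feature, 743 had more counts on the antisense feature, so the partner may be the main source. Each overlapped feature is therefore given with a partner where its value is first given, and such values are uncertain as to the gene. Values of mitochondrially encoded genes are uncertain as to the strand.

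Calls came from edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit with robust estimation and glmQLFTest), fitted once to all 17 libraries with a mean per condition. An adjusted p under 0.05 (Benjamini-Hochberg, over all 13510 features) was a call, with no minimum fold change. The 7 comparisons were the inhibitor against DMSO at each time, the difference between these responses, and 4 comparisons between conditions without inhibitor. The residual degrees of freedom were 11, and 9 with a replicate block. The block lowered the common coefficient of variation between libraries from 0.23 to 0.119. CPM are given as mean ± SD over the libraries of a condition, and log2 fold changes as value ± SE.

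Most libraries that share a letter deviated together from the means of their conditions. The correlation of these deviations across genes was 0.308, 0.534 and 0.22 for 4h_ATRi with 4h_DMSO in A, B and C, and 0.321 and 0.455 for 6h_ATRi with 6h_DMSO in A and B. Over the other pairs compared it ran from 0.138 to 0.511. The highest correlation with another letter was lower, except for A in 4h_DMSO against arrested cells (0.262 against 0.203) and in 6h_DMSO against arrested cells (0.227 against 0.184). Genes are not independent replicates. The letters were therefore taken to pair the libraries, and the fit with the experiment as a block is given beside a call or count in the text where it changes the call or moves the count by over 1.5 times. With a 6h_ATRi library or experiment B left out, 6h_ATRi has 1 library.

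The 17 gene lists cover G2 and mitosis (G2M), S phase (E2F), replication histones, p53 targets, the ATR pathway, homologous recombination and Fanconi, cholesterol synthesis, the ATF4 amino acid response, FOXO targets, immediate early genes, NF-kB, interferon, YAP and TEAD targets, ribosome biogenesis, mitochondrially encoded genes, retinal pigment epithelium, and other cell types. Lists, comparisons, tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, two-sided, and adjusted over all 112 tests of 16 lists. The same test with an estimated correlation is given beside it. The replication histone list had 2 tested members and was not tested.

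Per comparison, the rule named the 6 largest rises and the 6 largest falls among called genes with an average log2 CPM of at least 2, a symbol, and every library of one condition above every library of the other. Chance gives 10% of genes such a separation with 3 against 3 libraries and 20% with 2 against 3. A panel of 17 genes and the 2 to 4 members of a list with the smallest p were added. Other genes are said to be chosen after their values were seen.

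List levels are means of log2 CPM over the tested members in a library, with a prior count of 2. They were compared by exact two-sided permutation tests in SciPy 1.17.1, whose smallest p is 0.1 with 3 against 3 libraries and 0.2 with 2 against 3. Overlaps between comparisons were set beside the number for independent lists and beside 20 simulations of unchanged groups.

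The fits were tested on simulated data with 200 changed genes, drawn 3 times from the means and library sizes of the 4 h and 6 h inhibitor comparisons (13510 genes each). The changed genes were taken from those with an average log2 CPM of at least 2, so recovery of lower genes was not covered. At 4 h edgeR recovered 0.5%, 18.9% and 64.6% of genes changed by 0.5, 1 and 2 on the log2 scale, and with the replicate block 16.4%, 44.3% and 87.9%. At 6 h these shares were 0%, 12.9% and 57.6%, and 10.9%, 35.3% and 79.8% with the block. False calls with the block were 3% of calls at 4 h and 5.6% at 6 h. The draw left out the gene-wise spread that glmQLFit adds, so the shares recovered may be too high and the shares of false calls too low.

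Alternatives were the replicate block, DESeq2 1.42.0, other scaling factors, no filter, fits of only the groups compared, another prior count and each library left out in turn. Fits with a library or experiment B left out had no replicate block unless it is named. With 1 library left out, list tests were adjusted over the comparisons which that library enters. Leaving out experiment B, the split by overlap on the opposite strand, and lists made of the features opposite to list members were added after the data were seen. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and plots drawn with matplotlib 3.10.9.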

Results

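Transcript levels were measured in RPE-1 cells, a near-diploid human retinal pigment epithelial line, moving through S phase and G2 with the kinase ATR active or inhibited. ATR is the checkpoint kinase that responds to stalled replication forks and restrains CDK1. A thymidine block depletes dCTP and holds cells at the start of S phase, and washing it out releases them together. The inhibitor AZ20 (2 µM) or DMSO was present from 1 h after the wash, for 3 h in cells collected at 4 h (late S phase) and for 5 h in cells collected at 6 h (G2). Per the series' design text, the question was which genes ATR controls through transcription. There were 3 libraries each of arrested cells, cycling cells, 4h_DMSO, 4h_ATRi and 6h_DMSO, and 2 of 6h_ATRi, with totals from 1758747 to 2357561 counts.

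Features on the strand opposite to abundant genes held more counts than the genes themselves. VIM, the intermediate filament vimentin, had 1095 ± 133 CPM (SD, n = 17), and VIM-AS1 opposite to it had 31320 ± 3614. GAPDH, the glycolytic enzyme, had 673 CPM against 35490 on AC006064.4, and the tubulin gene TUBA1B had 195 against 23410 on TUBA1B-AS1. The ferritin gene FTH1 had 131 CPM, and the retinal channel gene BEST1, whose exon overlaps it, had 12660. For the mitotic kinase PLK1 the values were 18.9 ± 10.7 on the gene, 422 ± 247 on AC008870.3 and 57.9 on ERN2. Of 1001 pairs of a coding gene and an antisense feature, 743 (74.2%) had more counts on the antisense feature, with a median ratio of 5.6. In mitochondria, MT-ND6, encoded on the light strand, had 12040 CPM and lay above MT-CO1, MT-CO2, MT-CO3 and MT-CYB in 17 of 17 libraries. The heavy-strand gene MT-ND5 had 11080 CPM and lay below MT-ND6 in 9 of 17. Counts on heavy-strand mitochondrial genes are therefore uncertain as to the strand they come from. Features overlapped on the opposite strand took 77.9% of all counts, and genes without such an overlap took 14.6%. Across genes, the fold changes of 692 coding genes and their antisense partners had correlations of 0.252 and 0.19 in the inhibitor comparisons at 4 h and 6 h, and 0.408 for 6h_DMSO against arrested cells. With shuffled partners they lay between -0.066 and 0.028.

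**Figure D1:**
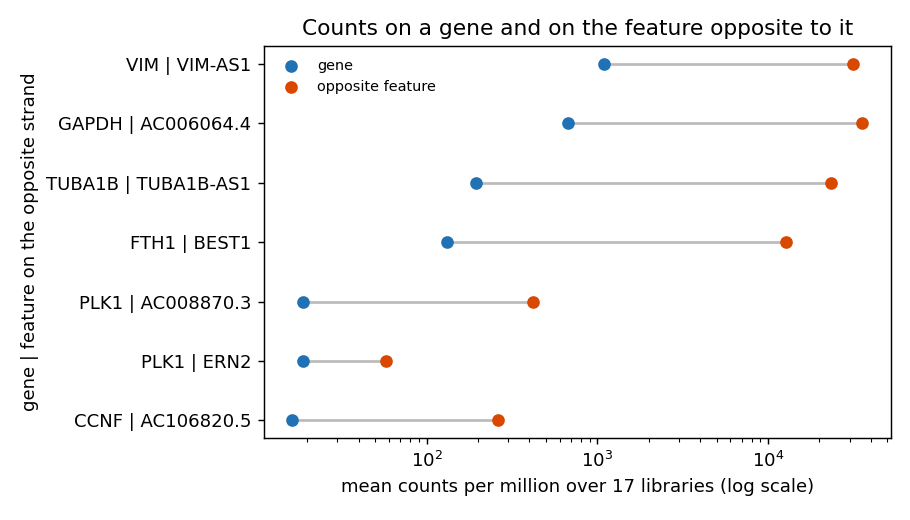
Mean CPM over 17 libraries (log axis) of 6 genes in blue and of 7 features on the opposite strand in orange, joined in pairs. VIM has a mean of 1095 and VIM-AS1 of 31320, and PLK1 has 18.9 against 422 on AC008870.3.

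The first principal component (27% of variance) set experiment B apart from A and C. The second (11.4%) parted arrested and cycling cells from released cells, with overlap between conditions on either side. B had scores of 21.7 to 51.7 on the first, and A and C had -28.2 to -12.2. On the second, arrested cells lay at 25.1 to 30.8, cycling cells at 16.9 to 27.3, 4h_DMSO at -9.8 to 3, 6h_DMSO at -21.1 to -4.9, 4h_ATRi at -25.4 to -13.3 and 6h_ATRi at -24.5 and -11.9. Libraries of B had more counts on the nuclear RNA NEAT1 (46.3 to 104 CPM against 11.7 to 42.7) and on the mitochondrial ribosomal RNA MT-RNR1 (224 to 292 CPM against 33.3 to 131). MT-RNR2 lay at 559 to 773 CPM in B and at 262 to 535 in A and C. A single ID, ENSG00000226958, took 7.04% to 11.5% of the counts in B and 1.3% to 4.48% elsewhere. Every condition has a library in B.

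**Figure D2:**
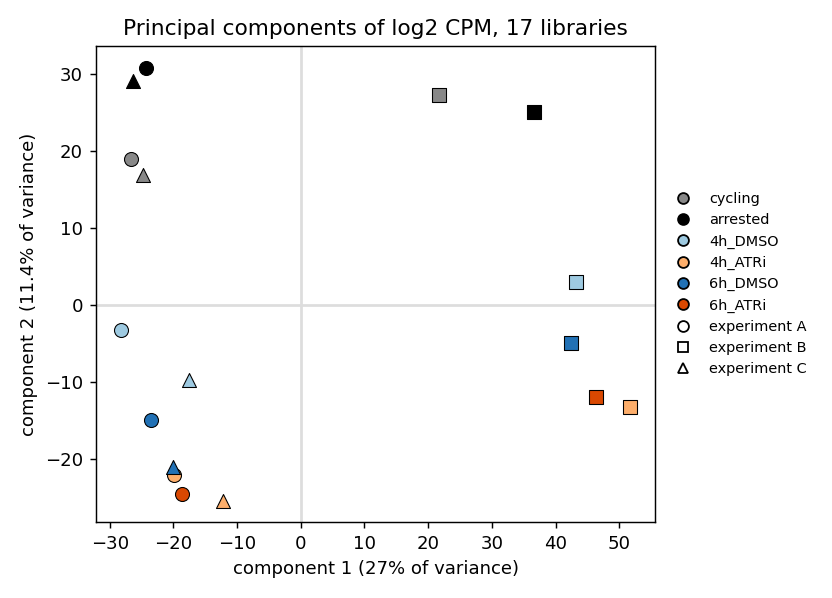
Scores of the 17 libraries on the first and second principal components of log2 CPM, with colour for the condition and shape for the experiment. Experiment B lies at 21.7 to 51.7 on the first axis, and 4h_ATRi lies at -25.4 to -13.3 on the second.

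At 4 h of release, in late S phase, inhibited cells held more transcripts of mitotic genes than DMSO cells. CENPF, a kinetochore protein, rose from 69.4 ± 5.17 to 134 ± 7.97 CPM (SD, n = 3 each; log2 0.95 ± 0.17, adjusted p = 0.00402). KIF14, a kinesin of cytokinesis, rose from 5.78 ± 0.537 to 22.2 ± 3.81 CPM (log2 1.93 ± 0.39, adjusted p = 0.0209). PLK1 rose from 10.9 ± 1.8 to 31.5 ± 6.4 CPM (log2 1.53 ± 0.30, adjusted p = 0.0125). The kinetochore motor CENPE rose by 1.60 ± 0.34 (adjusted p = 0.0491) and FAM83D, which brings casein kinase 1 to the spindle, by 1.56 ± 0.31 (adjusted p = 0.0181).

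Of 96 measured members of the G2M list at 4 h, 14 rose, none of the others fell, and 82 did not pass the test; 52 rose when adjusted over the list alone and 31 with the replicate block. The list as a whole rose (camera adjusted p = 4.15e-49, median log2 0.71, 89 of 96 members positive). Of 36 features opposite to its members 9 rose, 27 did not pass, and the group rose (adjusted p = 6.70e-30, and 0.0332 with an estimated correlation). Among those called, chosen after their values were seen, AC008870.3 (opposite PLK1) rose by 1.43 ± 0.20, CLCC1 (opposite GPSM2) by 1.29 ± 0.18, ERN2 (opposite PLK1) by 1.52 ± 0.23, GNB3 (opposite CDCA3) by 1.20 ± 0.19 and AC106820.5 (opposite CCNF, cyclin F) by 1.09 ± 0.17, each with an adjusted p of at most 0.00132. Panel genes that did not pass were CCNB1, cyclin B1 (log2 1.01 ± 0.38, adjusted p = 0.625), AURKA (1.04 ± 0.40, 0.681), CDK1 (0.72 ± 0.40), CDC25C (0.22), FOXM1 (0.31), CCNA2 (-0.17), E2F1 (-0.35), CCNE2 (-0.31), CDC6 (-1.70 ± 0.79), RRM2 (-0.32), CDKN1A (-0.48) and MDM2 (0.22). Of these, CDC25C is overlapped by FAM53C, FOXM1 by ITFG2, CCNA2 by EXOSC9, CCNE2 by INTS8, CDKN1A by ENSG00000285244 and MDM2 by AC025423.4. CCNB1 had only 3 to 34 counts per library. Its 4h_ATRi libraries (8.66 to 10.9 CPM) all lay above its 4h_DMSO libraries (3.45 to 5.95 CPM). A gene that did not pass at such counts cannot be called unchanged. KIF20A (overlapped by BRD8 and CDC23; 1.04 ± 0.27, adjusted p = 0.128) and the phosphatase CDC25B (1.11, adjusted p = 0.364) passed with the replicate block (adjusted p = 0.00304 and 0.00828).

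Among called features, the largest rise at 4 h was that of INSIG1, an endoplasmic reticulum protein that retains the sterol sensor SCAP, from 1.82 ± 0.764 to 14.0 ± 3.49 CPM (log2 2.90 ± 0.48, adjusted p = 0.00198). The membrane-shaping protein ARL6IP1 rose by 2.14 ± 0.41 (adjusted p = 0.0118), the dynein regulator NDE1 (overlapped by MYH11) by 1.88 ± 0.40 (adjusted p = 0.0285) and UBALD2 by 1.63 ± 0.22 (adjusted p = 2.92e-04). The PPIL2 feature, named for a cyclophilin-like ubiquitin ligase, rose from 22.1 ± 5.11 to 73.8 ± 21.2 CPM (log2 1.73 ± 0.25, adjusted p = 3.05e-04). It is overlapped by YPEL1, from which its reads may come. WEE1, the kinase that inhibits CDK1, rose by 1.47 ± 0.27 (adjusted p = 0.00813) and was the sole called member of 23 on the ATR pathway list, which as a whole did not pass (adjusted p = 0.657). With the replicate block RAD1 (overlapped by BRIX1) was lower as well (-0.53, adjusted p = 0.744, and 0.0354 with the block). The 14 features opposite to members of the ATR pathway list fell as a group (camera adjusted p = 0.0131 with the preset correlation). SARM1, an NAD-cleaving enzyme overlapped by SLC46A1, fell (log2 -0.90 ± 0.20, adjusted p = 0.0499). The other falls, named after their values were seen, were AL354864.1 opposite CLSPN, the claspin gene (-0.80 ± 0.17, adjusted p = 0.0285), and AC093484.4 (-1.54, adjusted p = 0.0491).

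Among other lists at 4 h, cholesterol synthesis genes rose as a group (adjusted p = 0.00305, but adjusted p = 0.0886 with an estimated correlation). INSIG1 was the 1 called member of 15 (2 with the replicate block). S phase genes fell as a group (adjusted p = 0.00861, but adjusted p = 0.188 with an estimated correlation), with 0 of 68 called by edgeR, 1 higher and 4 lower at an unadjusted p under 0.05, and 0 called by DESeq2. With the replicate block 1 was called, against the group: TMPO (overlapped by TMPO-AS1; 0.44, adjusted p = 0.796, and 0.0114 with the block). Its members with the smallest p were the chromatin remodeller HELLS (-1.04 ± 0.39, adjusted p = 0.615) and the histone chaperone subunit CHAF1A (overlapped by UBXN6; -0.71, adjusted p = 0.615). Ribosome biogenesis genes, such as NOP2 (-1.31 ± 0.39, adjusted p = 0.296) and POLR1C (overlapped by XPO5; -0.75), fell as a group (adjusted p = 0.00345, but adjusted p = 0.0886 with an estimated correlation). FOXO targets, such as CCNG2 (1.88, adjusted p = 0.313) and CDKN1B (0.89), rose as a group (adjusted p = 0.0466, but adjusted p = 0.173 with an estimated correlation and 0.0905 with the replicate block). The p53 targets did not pass (adjusted p = 0.766), nor did homologous recombination and Fanconi genes (0.952), the ATF4 response (0.902), immediate early genes (0.176), NF-kB (0.25), interferon (0.689), YAP and TEAD targets (0.84), mitochondrially encoded genes (0.888), retinal pigment epithelium (0.967) or other cell types (0.967). The 10 features opposite to immediate early genes rose as a group (camera adjusted p = 3.19e-04 with the preset correlation).

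In all, edgeR called 39 features higher and 3 lower at 4 h, and 162 and 75 with the replicate block; 25 of the 39 are overlapped on the opposite strand. Each of the 39 and 3 was also called with the block. In fits without it, the count was 17 without 4h_ATRi A, 26 without 4h_DMSO A and 23 without 4h_ATRi B. It was 20 without 4h_DMSO B, 13 without 4h_DMSO C and 85 with experiment B left out. With 1 library left out the calls of INSIG1, PPIL2, UBALD2 and CENPF held in every fit, while those of ARL6IP1, KIF14, CENPE (adjusted p = 0.14, 0.141 and 0.231 without 4h_ATRi A), NDE1 (0.22 without 4h_DMSO A), PLK1 and FAM83D (0.121 and 0.147 without 4h_DMSO C) and SARM1 (0.288 without 4h_ATRi B) ended in 3 or more fits. So did those of AL354864.1 (0.193) and AC093484.4 (0.452), highest without 4h_DMSO A, and that of WEE1 ended without 4h_DMSO B (0.0901) or 4h_DMSO C (0.0586). Group calls ended for S phase without 4h_DMSO A (adjusted p = 0.321), 4h_ATRi B (0.25) or experiment B (0.0558), for cholesterol synthesis without 4h_ATRi A (0.0751) or 4h_DMSO B (0.0532), and for ribosome biogenesis without 4h_ATRi B (0.098). Those of FOXO targets ended without 4h_ATRi A (0.166), 4h_DMSO A (0.18), 4h_DMSO B (0.0532), 4h_ATRi C (0.225) or 4h_DMSO C (0.0728).

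**Figure D3:**
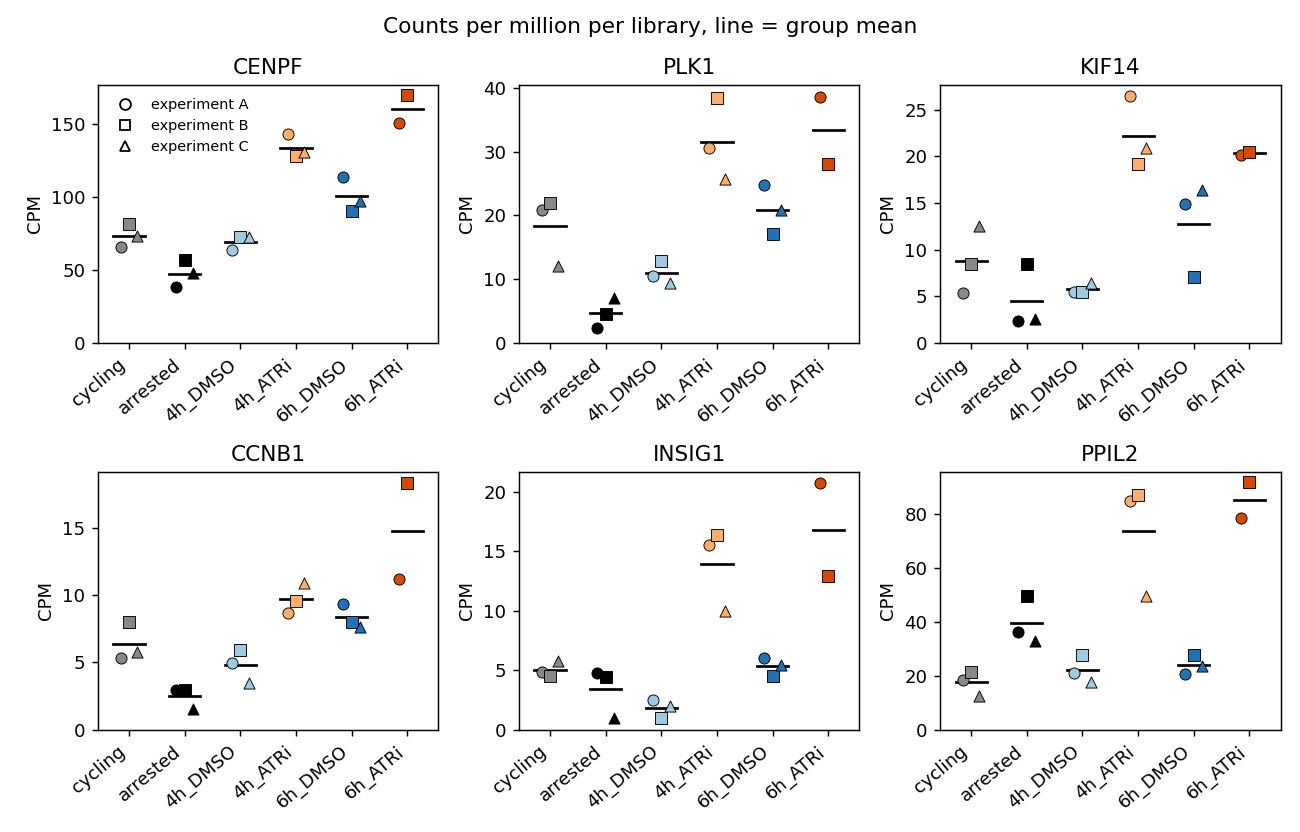
CPM of CENPF, PLK1, KIF14, CCNB1, INSIG1 and PPIL2 in each library, by condition, with a line at each mean. CENPF has a mean of 69.4 in 4h_DMSO and 134 in 4h_ATRi, and PPIL2 has 22.1 and 73.8.

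At 6 h of release, in G2, PPIL2 was the 1 feature called without the replicate block, and 55 features were higher and 17 lower with it. PPIL2 rose from 23.9 ± 3.57 CPM (SD, n = 3) to 85 ± 9.36 CPM (SD, n = 2), with a log2 change of 1.83 ± 0.26 (adjusted p = 0.00261). Mitotic genes rose again as a group: the G2M list had an adjusted p of 5.23e-17 (median log2 0.35, 83 of 96 members positive). CENPF had a log2 change of 0.68 ± 0.18 (adjusted p = 0.479, and 0.00663 with the replicate block), and UBE2S, the chain-elongating enzyme of the anaphase-promoting complex, had 0.94 ± 0.17 (adjusted p = 0.0734, and 5.42e-06 with the block). CEP55 of the midbody and the condensin subunit NCAPD2 (overlapped by MRPL51) also passed only with the block (0.89 and 0.59; adjusted p = 0.0224 and 0.00778). Of the 96 members, edgeR called 0, with 23 higher at an unadjusted p under 0.05; DESeq2 called 2, the test adjusted over the list alone 2 and the block 4.

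Cholesterol synthesis genes rose as a group at 6 h (adjusted p = 0.00199, but adjusted p = 0.0886 with an estimated correlation); edgeR and DESeq2 called 0 of 15, with 3 at an unadjusted p under 0.05. INSIG1 had a log2 change of 1.64 ± 0.44 (adjusted p = 0.517). YAP and TEAD targets, such as ANKRD1 (-0.64) and CCN1 (-0.66), fell as a group (adjusted p = 7.13e-04, but adjusted p = 0.245 with an estimated correlation). Ribosome biogenesis genes, such as the nucleolar methyltransferase FBL (-0.79), fell as a group (adjusted p = 0.0169, but adjusted p = 0.156 with an estimated correlation and 0.06 with the replicate block). Mitochondrially encoded genes passed only with the block (adjusted p = 0.881, and 0.00918 higher with it), but not with the block and an estimated correlation. S phase genes did not pass (adjusted p = 0.657), nor did p53 targets (0.697), the ATR pathway (0.979), homologous recombination (0.705), the ATF4 response (0.888), FOXO targets (0.84), immediate early genes (0.322), NF-kB (0.98), interferon (0.888), retinal pigment epithelium (0.63) or other cell types (0.888). Panel genes that did not pass included CCNB1 (0.82), AURKA (1.24 ± 0.41, adjusted p = 0.743), PLK1 (0.67), CENPE (0.67), KIF20A (0.87), FOXM1 (0.48), CDK1 (0.17), E2F1 (-1.56), CDC6 (1.55), RRM2 (0.07), CDKN1A (0.32) and MDM2 (0.44). As at 4 h, genes with few counts cannot be called unchanged.

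Beside the 1 call of edgeR at 6 h, 648 features had an unadjusted p under 0.05, DESeq2 called 17 higher and 2 lower, and the replicate block 55 higher and 17 lower. PPIL2 lost its call without 6h_ATRi B (adjusted p = 0.0502), and the count was 2 without 6h_DMSO A or without 6h_ATRi B and 25 with experiment B left out. Without 6h_ATRi A, 6h_ATRi B or experiment B that condition has 1 library, and the spread comes from the other conditions. The cholesterol call ended without 6h_ATRi A (adjusted p = 0.739), and that of ribosome biogenesis without 6h_ATRi A (0.0967), 6h_DMSO A (0.0576) or 6h_DMSO C (0.0701).

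The response of mitotic genes was smaller at 6 h than at 4 h by the test of the difference itself. The G2M list differed (adjusted p = 6.23e-09, median log2 -0.35; 0.0306 with an estimated correlation, but 0.0599 with the block as well), with 0 of 96 members called by edgeR or DESeq2 and 6 lower at an unadjusted p under 0.05. KIF14 had a difference of -1.26 and did not pass. YAP and TEAD targets (adjusted p = 0.00152) and immediate early genes (adjusted p = 0.0369) also differed downward, with adjusted p = 0.266 and 0.327 with an estimated correlation and, for immediate early genes, 0.0672 with the replicate block. Mitochondrially encoded genes differed upward only with the block (adjusted p = 0.766, and 0.00163 with it), but not with the block and an estimated correlation. For single features edgeR called 0, with 401 at an unadjusted p under 0.05; DESeq2 called 0, with 346. With the replicate block 6 features passed, all lower, and 2 higher and 2 lower with experiment B left out as well, when 6h_ATRi has 1 library. Of these, TWIST1, a transcription factor of mesenchymal cells overlapped by AC003986.2, had a difference of -1.78 ± 0.39 (adjusted p = 0.0219), and DIS3 (opposite BORA, the activator of PLK1) had -1.12 ± 0.17 (adjusted p = 7.58e-06).

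The call of immediate early genes for this difference ended without 4h_ATRi A (adjusted p = 0.269), 4h_DMSO A (0.237), 6h_ATRi A (0.721), 6h_DMSO B (0.089), 4h_ATRi C (0.225) or 6h_DMSO C (0.123), and that of YAP and TEAD targets without 4h_ATRi C (0.109). The other 13 lists did not pass, from S phase (adjusted p = 0.299) to the ATF4 response (0.919).

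Between 4 h and 6 h without inhibitor, transcripts of the mitotic apparatus rose as cells passed from late S phase to G2. SAPCD2, a regulator of spindle orientation overlapped by AL807752.3, rose from 3.96 ± 1.31 to 18.2 ± 3.11 CPM (SD, n = 3 each; log2 2.18 ± 0.38, adjusted p = 0.00721). ERN2 (opposite PLK1) rose by 1.63 ± 0.23 and CLCC1 (opposite GPSM2, which orients the spindle) by 1.30 ± 0.18 (adjusted p = 2.98e-04 each). GNB3 (opposite CDCA3) rose by 1.10 ± 0.19, MSC-AS1 (overlapped by MSC and TRPA1) fell (log2 -1.27 ± 0.22), and VIL1 (opposite the deubiquitinase gene USP37) fell (-0.91 ± 0.16), each with an adjusted p of 0.00663. Other rises, chosen after their values were seen, were AC005339.1 (opposite TNFAIP8L1, 1.85), AC008870.3 (opposite PLK1, 1.39), AL807752.3 (opposite SAPCD2, 1.36), AL138789.1 (opposite DEPDC1, 1.13) and AP000648.3 (0.85).

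The G2M list rose as a group from 4 h to 6 h (adjusted p = 7.53e-35, median log2 0.58). Of its 96 members edgeR called 0, with 46 higher at an unadjusted p under 0.05; DESeq2 called 3, the test adjusted over the list alone 28 and the replicate block 15. TOP2A, topoisomerase II, had a log2 change of 0.78 ± 0.17 (adjusted p = 0.0808, and 1.65e-04 with the block). S phase genes fell as a group (adjusted p = 4.80e-04, but adjusted p = 0.0886 with an estimated correlation), and the licensing factor CDC6 had -3.70 ± 0.99 (adjusted p = 0.263, and 0.0157 with the block). The ATF4 response fell as a group (adjusted p = 0.00152, but adjusted p = 0.251 with an estimated correlation), as did mitochondrially encoded genes (adjusted p = 1.86e-04, but adjusted p = 0.333 with an estimated correlation). In the panel, CENPE (1.25 ± 0.35), CENPF (0.53 ± 0.17) and CDC25B (1.07) passed only with the block (adjusted p = 0.00158, 0.0262 and 0.0119), while CCNB1 (0.80), PLK1 (0.94) and AURKA (0.67) did not pass.

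From 4 h to 6 h edgeR called 9 features higher and 2 lower, and 88 and 53 with the replicate block; the count was 7 without 6h_DMSO A and 82 with experiment B left out. Calls ended for SAPCD2 without 4h_DMSO B (adjusted p = 0.0632), for GNB3 without 6h_DMSO A (0.0849) or 4h_DMSO C (0.115), and for MSC-AS1 without 4h_DMSO A (0.0855) or 6h_DMSO A (0.0849). Those of AL138789.1 (0.184 without 6h_DMSO A) and AP000648.3 (0.184 without 4h_DMSO A) ended in 3 or more fits. Group calls ended for S phase without 4h_DMSO A (0.0592), for the ATF4 response without 6h_DMSO B (0.137) or 4h_DMSO C (0.0565), and for mitochondrially encoded genes without 4h_DMSO C (0.142).

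At 4 h after release with DMSO, the largest changes from arrested cells by the rule were of genes with varied functions. Arrested cells were not released, and the labels give them no washes and no DMSO. Release, the washes and DMSO therefore differ together in this comparison and in that at 6 h. The BMP antagonist GREM1 (overlapped by GREM1-AS1) rose from 34.9 ± 4.87 to 109 ± 8.33 CPM (SD, n = 3 each; log2 1.65 ± 0.21, adjusted p = 1.31e-04), and the receptor GPR176 by 1.78 ± 0.31 (adjusted p = 0.00355). Spindle genes PSRC1 (2.72 ± 0.59) and FAM83D (2.02 ± 0.44) rose with an adjusted p of 0.0246 each, ICAM4-AS1 (overlapped by ICAM1 and ICAM4) by 2.72 ± 0.57 (0.0237) and the helicase DHX37 by 1.62 ± 0.39 (0.0436). DDIT4-AS1, opposite the mTORC1 inhibitor gene DDIT4, fell from 903 ± 222 to 160 ± 30.6 CPM (log2 -2.50 ± 0.32, adjusted p = 0.00135). DHRS3, a retinal reductase, fell (-1.99 ± 0.36, adjusted p = 0.00481), as did TBPL1 (opposite SLC2A12; -1.86 ± 0.27, adjusted p = 4.97e-04), the chemokine receptor gene CCR7 (-1.83 ± 0.39, 0.021), PHYHIPL (overlapped by FAM13C; -1.63, 0.0101) and the histone pseudogene H2BC20P (overlapped by H2BC19P; -1.39 ± 0.22, 7.12e-04), whose reads may belong to a near-identical histone gene.

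YAP and TEAD targets rose as a group at 4 h (adjusted p = 1.61e-07, but adjusted p = 0.0886 with an estimated correlation). Of 20 members 3 rose, 6 when adjusted over the list alone and 7 with the replicate block, among them the matrix protein CCN2 (overlapped by AL133346.1; 0.99 ± 0.21, adjusted p = 0.0245) and ANKRD1 (0.90 ± 0.20, 0.0262). Immediate early genes rose as a group (adjusted p = 4.08e-05, but adjusted p = 0.0886 with an estimated correlation); 2 of 27 rose, CCN2 and the transcription factor KLF2 (1.48 ± 0.27, adjusted p = 0.00576), with 8 when adjusted over the list alone and 6 with the block. The G2M list rose (adjusted p = 7.25e-06, but adjusted p = 0.0886 with an estimated correlation), with 6 of 96 called (16 with the block), including KPNA2 (1.17, adjusted p = 0.0196) and UBE2S (0.85, adjusted p = 0.0131). The p53 targets fell as a group (adjusted p = 2.08e-06, but adjusted p = 0.149 with an estimated correlation), with 0 of 35 called by edgeR or DESeq2, 5 lower at an unadjusted p under 0.05 and 3 lower with the block. S phase genes fell (adjusted p = 0.0142, but adjusted p = 0.228 with an estimated correlation), with CCNE2 the 1 member called with the block, as did retinal pigment epithelium genes (adjusted p = 0.0463, but adjusted p = 0.251 with an estimated correlation). Interferon genes fell (adjusted p = 0.00104), with 0 of 9 called by edgeR or DESeq2, 2 lower at an unadjusted p under 0.05 or with the block, and IFIT3 at -1.34. Mitochondrially encoded genes rose (adjusted p = 5.49e-12, but adjusted p = 0.0886 with an estimated correlation): MT-ND1 (1.18 ± 0.21, adjusted p = 0.00569) and MT-ND2 (1.07 ± 0.20, adjusted p = 0.00576) rose, and MT-ND6 of the other strand fell (-0.71 ± 0.17, adjusted p = 0.0361), and with the block 7 of 15 rose and 1 fell. Given the strand pattern, and since MT-ND6 went the other way, the direction for mitochondrial RNA is uncertain.

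At 6 h, when the DMSO cells had reached G2, mitotic genes were among the largest rises over arrested cells. FAM83D rose from 1.57 ± 0.428 to 17.6 ± 3.9 CPM (log2 3.43 ± 0.40, adjusted p = 5.25e-06), the centromeric histone CENPA from 0.702 ± 0.276 to 9.64 ± 2.99 CPM (3.66 ± 0.57, 3.01e-04), and PSRC1 by 3.70 ± 0.55 (2.21e-04). Other rises by the rule were VWA3B (3.27 ± 0.54, adjusted p = 5.97e-04), C19orf33 (3.35 ± 0.83, 0.0269) and the mitochondrial transfer RNA MT-TM (3.07 ± 0.82, 0.041). BBC3, the p53 target that encodes the apoptosis inducer PUMA, fell (-2.66 ± 0.54, adjusted p = 0.00463), as did MIR3190 (overlapped by BBC3; -3.26 ± 0.73, 0.012), SESN2 (-2.96 ± 0.80, 0.0446), DDIT4-AS1 (-3.14 ± 0.33, 9.05e-05), INTS8 (opposite CCNE2, cyclin E2; -2.70 ± 0.54, 0.0224) and PHYHIP (-2.68, 0.0325).

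Of the G2M list 35 of 96 rose at 6 h and none of the others fell; 54 rose and 1 fell when adjusted over the list alone, and 47 and 1 with the replicate block; the group rose (adjusted p = 2.06e-34, median log2 0.93), led by KPNA2 (2.05 ± 0.24, adjusted p = 5.25e-06) and HJURP, the loader of CENPA overlapped by MROH2A (2.22, adjusted p = 3.03e-05). S phase genes fell (adjusted p = 8.32e-07, median log2 -0.48): 2 of 68 passed, thymidylate synthase TYMS (overlapped by ENOSF1; -0.83 ± 0.19, adjusted p = 0.0127) and the helicase subunit MCM3 (-1.38 ± 0.34, adjusted p = 0.0229), with 11 when adjusted over the list alone and 10 with the replicate block. The p53 targets fell as a group (adjusted p = 7.86e-07, but adjusted p = 0.127 with an estimated correlation), with BBC3 and SESN2 the called members of 35 (8 with the block). YAP and TEAD targets (adjusted p = 3.40e-05, but adjusted p = 0.156 with an estimated correlation), immediate early genes (adjusted p = 0.0132, but adjusted p = 0.273 with an estimated correlation) and mitochondrially encoded genes (adjusted p = 5.44e-04, but adjusted p = 0.364 with an estimated correlation) rose as groups. Called members included KLF6 (2.27, adjusted p = 0.00476), KLF2 (1.27, 0.00954), ANKRD1 (0.82, 0.0245), CRIM1 (overlapped by AC007378.1; 0.73, 0.0306), MT-ND2 (0.95, 0.00582) and MT-CO3 (1.07, 0.0325). MT-ND6 fell (-0.72, adjusted p = 0.0141), so the direction for mitochondrial RNA is uncertain here too; of 15 members 3 were higher and 1 lower, and 5 and 1 with the block. Retinal pigment epithelium genes passed only with the replicate block (adjusted p = 0.127, and 0.0206 lower with it), but not with the block and an estimated correlation. Interferon genes did not pass (0.163). The remaining lists did not pass in either comparison with arrested cells.

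Against arrested cells edgeR called 56 features higher and 44 lower at 4 h (304 and 340 with the replicate block) and 171 and 143 at 6 h (509 and 532 with it). DESeq2 called 188 at 4 h, and with experiment B left out the counts were 418 and 771. At 4 h the count was 29 without arrested A, 26 without arrested C and 33 without 4h_DMSO C, and at 6 h 160 without arrested A, 187 without 6h_DMSO A, 146 without arrested C and 143 without 6h_DMSO C. With 1 library left out, calls of GREM1, GPR176, DDIT4-AS1, DHRS3, TBPL1 and H2BC20P at 4 h, and of PSRC1, CENPA, FAM83D, VWA3B, DDIT4-AS1 and BBC3 at 6 h, held in every fit. Those of the other genes named by the rule ended, with the highest adjusted p for ICAM4-AS1 (0.115), DHX37 (0.204) and CCR7 (0.105) without 4h_DMSO C, for PSRC1 (0.126) and PHYHIPL (0.0863) without arrested C, and for FAM83D (0.155) with experiment B left out. At 6 h it was highest for C19orf33 (0.116), MT-TM (0.213) and INTS8 (0.0863) without arrested C, MIR3190 (0.0852) without arrested B, SESN2 (0.192) without 6h_DMSO A and PHYHIP (0.285) without arrested A. Called members of lists also lost their calls. At 4 h the highest adjusted p was 0.204 for CCN2, 0.18 for KPNA2, 0.139 for UBE2S and 0.0541 for MT-ND1 without arrested C. It was 0.24 for ANKRD1, 0.0983 for KLF2 and 0.0703 for MT-ND2 without 4h_DMSO C, and 0.23 for MT-ND6 without arrested A. At 6 h both S phase calls ended, that of TYMS without 6h_DMSO C (0.119) or arrested A (0.0707) and that of MCM3 in 4 fits (highest 0.126 without 6h_DMSO B). KLF2 (0.099), CRIM1 (0.245), MT-CO3 (0.153) and MT-ND2 (0.0524) ended there without 6h_DMSO C, ANKRD1 (0.141) and KLF6 (0.0503) without arrested C, and MT-ND6 (0.117) without arrested A. Of the groups, S phase at 4 h lost its call without 4h_DMSO B (0.108), arrested C (0.0694), 4h_DMSO C (0.0728) or experiment B (0.056), and immediate early genes at 6 h without arrested C (0.0601). Retinal pigment epithelium at 4 h lost its call without arrested A (0.0648), 4h_DMSO B (0.246), arrested C (0.112), 4h_DMSO C (0.0772) or experiment B (0.0703).

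Cells arrested by thymidine differed from cycling cells in higher p53 targets and lower mitotic genes. CDKN1A, the CDK inhibitor p21, rose from 13.2 ± 4.33 to 78.4 ± 48.8 CPM (SD, n = 3 each; log2 2.57 ± 0.54, adjusted p = 0.0437), and the death receptor FAS (overlapped by ACTA2) from 66.4 ± 19.1 to 172 ± 34.3 CPM (1.37 ± 0.19, 1.10e-04). BBC3 rose by 3.37 ± 0.57 (adjusted p = 0.00156), MDM2, which degrades p53, by 1.35 ± 0.25 (0.00316), and AC025423.4 opposite MDM2, chosen after its values were seen, by 1.63 ± 0.17 (5.35e-06). Mitotic genes fell, with CENPA at -3.09 ± 0.59 (adjusted p = 0.00544), FAM83D at -2.67 ± 0.42 (5.68e-04), PSRC1 at -2.56 ± 0.60 (0.0302), PLK1 at -1.94 ± 0.35 (0.00279) and SAPCD2 at -1.92 ± 0.38 (0.00835), as did ERN2 opposite PLK1 (-1.96 ± 0.25, 2.71e-05). Other rises by the rule were the epidermal gene HRNR (5.01 ± 0.94, adjusted p = 0.029), the unconventional cyclin gene CCNG2 (3.43 ± 0.82, 0.0345), A4GNT (3.09, 0.0208) and GDNF-AS1 (overlapped by GDNF; 1.96 ± 0.32, 0.00199).

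Of 35 p53 targets 7 rose in arrested cells, 16 when adjusted over the list alone and 14 with the replicate block; the group rose (adjusted p = 3.52e-16, median log2 1.06). Of the G2M list 8 of 96 fell, 18 with the block, and 21 when adjusted over the list alone with 1 higher; the group fell (adjusted p = 1.99e-09, median log2 -0.44), with CDC20, the activator of the anaphase-promoting complex, at -1.72 (adjusted p = 0.00214) and UBE2S at -1.30 (3.47e-05). The ATF4 response rose as a group (adjusted p = 5.23e-06, but adjusted p = 0.108 with an estimated correlation), with 1 of 25 called (4 with the block), NUPR1 (1.27, adjusted p = 0.00673). FOXO targets rose (adjusted p = 0.00742, but adjusted p = 0.0886 with an estimated correlation), with 3 of 11 called (5 with the block): CCNG2, TXNIP (1.78, adjusted p = 0.0302) and the ubiquitin ligase gene FBXO32 (1.68, 0.0354). Ribosome biogenesis genes fell (adjusted p = 8.08e-04, but adjusted p = 0.0816 with an estimated correlation), as did mitochondrially encoded genes (adjusted p = 1.17e-04, but adjusted p = 0.327 with an estimated correlation), although MT-ND6 rose (0.70, adjusted p = 0.033). NF-kB and retinal pigment epithelium genes were higher only with the replicate block (adjusted p = 0.0691 and 0.0735, and 0.00404 and 0.0037 with it). Neither passed with the block and an estimated correlation. S phase genes did not pass (adjusted p = 0.705), nor did the remaining 7 lists. Of the replication histones 2 of 68 were measured, too few for a test.

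Between arrested and cycling cells edgeR called 81 features higher and 58 lower, and 379 and 383 with the replicate block; with experiment B left out the count was 264. It was 86 without arrested A, 50 without cycling A, 58 without arrested B, 64 without cycling B, 81 without arrested C and 68 without cycling C. With 1 library left out the calls of BBC3, GDNF-AS1, FAM83D, ERN2 and PLK1 held in every fit. Those of HRNR (adjusted p = 0.132), PSRC1 (0.218) and A4GNT (0.131) ended without cycling A, CCNG2 (0.161) and CDKN1A (0.167) without cycling C, CENPA (0.0506) and MDM2 (0.0537) without arrested B, and SAPCD2 (0.0942) without arrested C. Of the list members, TXNIP (highest 0.137 without arrested B) and FBXO32 (0.199 without cycling B) ended in 6 fits each, MT-ND6 in 5 (0.19 without cycling C) and NUPR1 in 3 (0.0612 without cycling B). FOXO targets lost their group call without arrested B (0.0553), cycling B (0.0519) or experiment B (0.169), and ribosome biogenesis without experiment B (0.0709). Over all comparisons, 9 of 36 list calls held with an estimated correlation: the G2M list in each comparison except 4h_DMSO against arrested cells, S phase in 6h_DMSO against arrested cells, p53 targets in arrested against cycling cells and interferon in 4h_DMSO against arrested cells. With the block as well, 4 of these 9 ended: interferon (adjusted p = 0.137) and, at 0.0599 each, S phase in 6h_DMSO against arrested cells and the G2M list in arrested against cycling cells and in the difference between the responses. For 4h_DMSO against arrested cells, p53 targets (0.0205) and mitochondrially encoded genes (0.0181) then passed.

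Averaged over its members, the G2M list was lowest in arrested cells and highest in cells inhibited until 6 h. Its mean log2 CPM was 3.53 ± 0.13 in arrested cells (SD, n = 3), 3.96 ± 0.02 in cycling cells, 3.83 ± 0.04 in 4h_DMSO, 4.53 ± 0.06 in 4h_ATRi, 4.38 ± 0.13 in 6h_DMSO and 4.76 ± 0.02 in 6h_ATRi (n = 2). The inhibitor added 0.69 at 4 h (0.66 to 0.71 within experiments; exact two-sided p = 0.1, the smallest that 3 against 3 libraries allow) and 0.38 at 6 h (0.26 within A and 0.50 within B; exact p = 0.2, the smallest for 2 against 3). 4h_ATRi lay 0.14 above 6h_DMSO (higher in 3 of 3 experiments, exact p = 0.2), but the 36 features opposite to members did not show this order (0.06, higher in 1 of 3 experiments, exact p = 0.7). The S phase list had 3.91 ± 0.07 in arrested cells, 3.87 ± 0.08 in cycling cells, 3.72 ± 0.11 in 4h_DMSO, 3.53 ± 0.08 in 4h_ATRi, 3.46 ± 0.05 in 6h_DMSO and 3.39 ± 0.10 in 6h_ATRi. It was lower by 0.19 with the inhibitor at 4 h (3 of 3 experiments, exact p = 0.1). At 6 h the difference was -0.065 (-0.179 within A and -0.009 within B, exact p = 0.4). Its size was below the SD of 6h_ATRi but not that of 6h_DMSO.

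**Figure D4:**
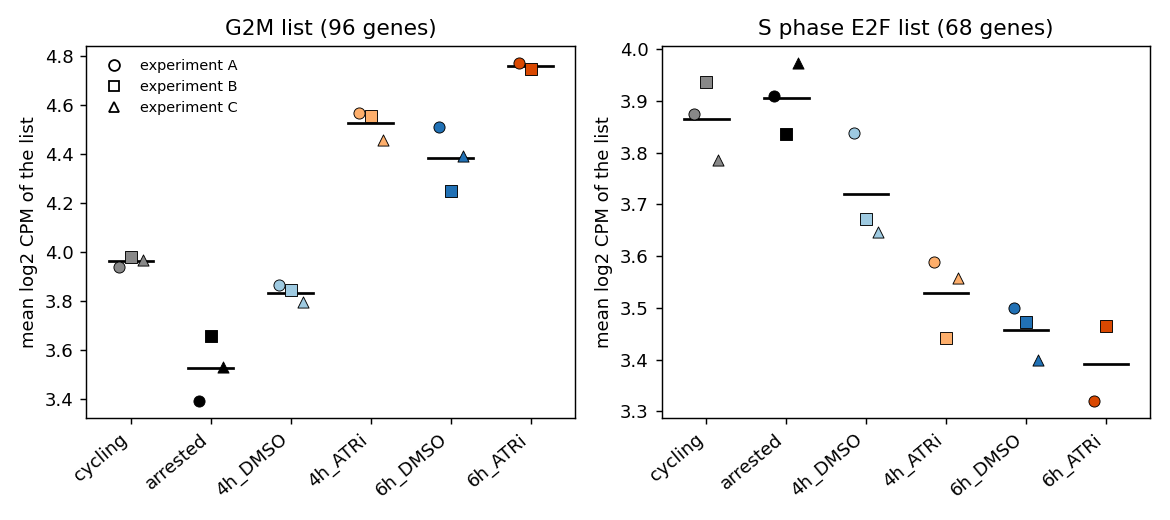
Mean log2 CPM of the G2M list (96 genes) and the S phase list (68 genes) in each library, by condition, with a line at each mean. The G2M list rises from 3.83 in 4h_DMSO to 4.53 in 4h_ATRi, and lies at 4.38 in 6h_DMSO.

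Many of the features that rose with the inhibitor at 4 h were also called higher in G2 than in the block. Of the 39 features higher at 4 h, 28 were higher in 6h_DMSO than in arrested cells, a comparison that shares no library with it, where independent lists would share 0.494; 1 of the 3 lower features was also lower there (0.0318 for independent lists). Without the G2M list and features opposite to it, 8 of 16 higher features were shared. With the replicate block 94 of 162 higher and 21 of 75 lower were shared (6.1 and 2.95 for independent lists), and 9 went opposite ways. Across all 13510 features the fold changes had r = 0.132 and a covariance of 0.0344, against 0.0011 and 2e-04 in simulated unchanged groups. With 6h_DMSO against 4h_DMSO, which shares the 4h_DMSO libraries, 7 higher features were shared (0.026 for independent lists), and 53 higher and 9 lower with the block. There r was 0.495, and 0.508 in simulated unchanged groups; the covariance was 0.1014 against 0.0969, a difference of 0.0045. The r lay within the range of the simulations (0.493 to 0.527), so the shared controls alone can account for it. The covariance lay just above their highest, 0.1002, and without the block they shared 0 calls. Part of the shared calls may still come from the shared controls. The 4 h and 6 h inhibitor comparisons shared 1 call, PPIL2 (r = 0.15, covariance 0.0354), and with the block 39 higher and 3 lower (0.66 and 0.0944 for independent lists).

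**Figure D5:**
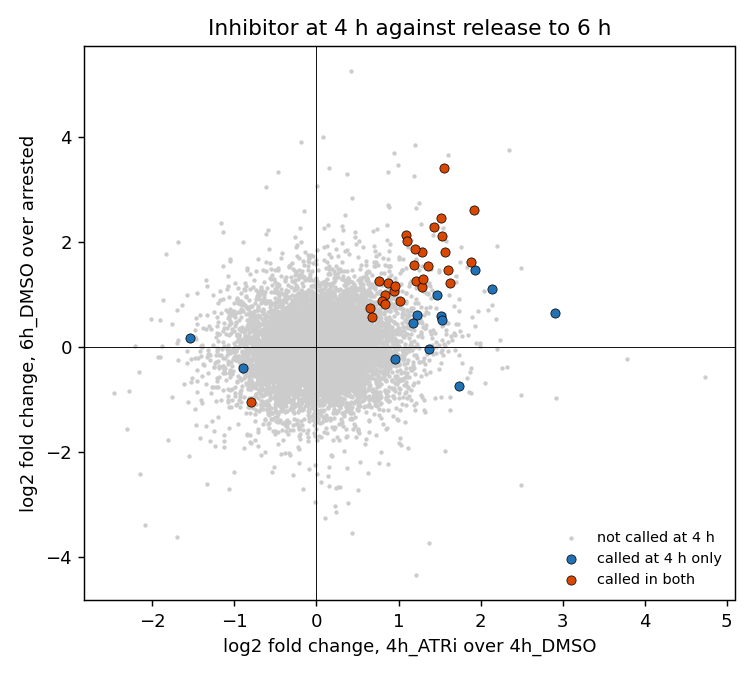
Log2 fold change of each of 13510 features for 4h_ATRi against 4h_DMSO (horizontal) and 6h_DMSO against arrested cells (vertical), with grey for features not called at 4 h, blue for those called at 4 h and orange for those called in both. The 29 orange points lie in the quadrants where both changes have one sign.

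The deposited fold change table calls 61 genes at 4 h (57 higher and 4 lower with the inhibitor), 17 at 6 h (15 and 2), 33 between 4h_DMSO and 6h_DMSO, 188 and 384 for 4h_DMSO and 6h_DMSO against arrested cells, and 199 for arrested against cycling cells. Of these, 40, 1, 10, 91, 262 and 133 were also called by edgeR, and 61, 16, 33, 187, 384 and 199 with the replicate block. The fold changes correlated across genes with r from 0.913 to 0.936.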

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

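The tests of the strand setting, of antisense transcription, of counting without strand, of depth, of chance values of the 4h_DMSO libraries, of overlapping reads and of the path in opposite features were chosen only after the results were seen. The tests of RNA without a poly(A) tail, of strand marking, of the path from 4 h to 6 h and of other splits were written before theirs.

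Mitotic genes stood higher after ATR inhibition at 4 h, and 29 calls were shared in direction with 6h_DMSO against arrested cells. No library is common to both, which argues against independent chance values of single genes in the 4h_DMSO libraries. If the 4h_DMSO cells lay behind in the cycle by chance, such calls would be shared too, so the test cannot decide on that. Members of the G2M list with no overlapped exon rose as a group (adjusted p = 1.05e-42), which argues against reads of overlapping genes. If inhibited cells only lay further along the path from 4h_DMSO to 6h_DMSO, both lists would move by an equal share of it, but the G2M share of 1.32 ± 0.378 (SD, n = 3 experiments) exceeded the S phase share of 0.75 ± 0.393 by 0.567 ± 0.194, with 0.358, 0.604 and 0.741 in A, B and C. Features opposite to the members, where most reads lie, gave differences of -0.556, 0.81 and -0.195 (mean 0.019 ± 0.708). The bound set beforehand, a difference over 2 SD with 1 sign, was met by the list members. It did not cover the opposite features, which were added after the results were seen and did not meet it. Faster progress along the path therefore stays open. A path that bends between the sampled times also stays open, as does a change in the share of cells near mitosis.

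More counts lay on features opposite to abundant genes than on the genes. In 74.2% of pairs of a coding and an antisense gene the antisense gene had more, which is consistent with stranded libraries counted with the opposite strand setting. Antisense transcription of its own was predicted to leave most counts on genes without a partner, which held at most 16.6% in any library. The share that correct counting would give was not estimated. Abundant genes such as VIM and GAPDH have a partner themselves, so this test cannot decide on antisense transcription. Counting without regard to strand would put MT-ND6 below the heavy-strand genes, and it lay above 4 of them in 17 libraries. MT-ND5, also of the heavy strand, lay below MT-ND6 in only 9 of 17 libraries, so the order does not hold for every heavy-strand gene. Beyond antisense transcription no biological explanation was tested, since the design gives none.

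Libraries of experiment B lay apart on the first component. Depth is argued against by 7 libraries of A and C whose totals fall inside the range of B and which lie on the other side of 0. Weaker strand marking as the whole reason is argued against: the lowest median share of a pair's counts on the coding gene in B minus the highest in A and C was -0.51 percentage points, and 2 libraries of A and C that reach the range of B lie on the other side of 0. B lay 0.35 to 2.74 points above the mean of A and C in 6 of 6 conditions, so weaker marking as a part of the difference stays open. More RNA without a poly(A) tail stays open: the ratio of replication histone CPM in B to the mean of A and C was lowest in 6h_DMSO at 0.62 and 1.16 to 2.37 in the other conditions, but the sums held only 47 to 222 counts per library over 64 genes, so the bound set beforehand, a ratio under 1 in any condition, was too strict for genes near the floor. No biological explanation was tested, since the labels name no difference between experiments.

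The responses to the inhibitor at 6 h and 4 h were compared by a test of the difference itself. The G2M list differed with an adjusted p of 6.23e-09 (0.0306 with an estimated correlation, but 0.0599 with the replicate block as well). Immediate early genes differed with an adjusted p of 0.0369 and YAP and TEAD targets with 0.00152, but both calls ended with an estimated correlation (0.327 and 0.266) and that of immediate early genes with the block (0.0672). With the replicate block 6 features differed, all with a smaller or opposite response at 6 h: DIS3 (1.12 at 4 h and 0.00 at 6 h), AC106820.5 (1.11 and 0.08), AC008870.3 (1.45 and 0.60), AC005339.1 (1.90 and 0.64), CLCC1 (1.30 and 0.58) and TWIST1 (0.86 and -0.93). With the block and experiment B left out 2 features were higher and 2 lower, but 6h_ATRi then has 1 library.

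Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many calls. The real split gave 42 calls at 4 h (highest of the others 0), 11 from 4h_DMSO to 6h_DMSO (0), 100 and 314 for 4h_DMSO and 6h_DMSO against arrested cells (2 and 0), and 139 for arrested against cycling cells (0). Of the other splits, those that part all 3 pairs of an experiment called 0, and the 2 calls came from a split that keeps the libraries of experiment B together.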

How the results depend on the processing

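The splits by overlap on the opposite strand, the lists of opposite features, the leaving out of experiment B and the overlaps without the G2M list were chosen only after the data were seen. The order of comparisons is 4h_ATRi against 4h_DMSO, 6h_ATRi against 6h_DMSO, the difference of these, 6h_DMSO against 4h_DMSO, 4h_DMSO and 6h_DMSO against arrested cells, and arrested against cycling cells. With the replicate block calls numbered 237, 72, 6, 141, 644, 1041 and 762, and every call of the fit without it was kept; besides the list calls named with their comparisons it changed no other list call. With the block and experiment B left out they numbered 122, 26, 4, 106, 549, 969 and 350. DESeq2 called 19 at 6 h, 33 from 4h_DMSO to 6h_DMSO and 188 for 4h_DMSO against arrested cells. Without a filter on low counts 10 and 34 were called for the first and second of these. Fitting only the groups compared gave 22, 2 and, for 4h_DMSO against arrested cells, 59. Genes with no overlapped exon gave 2, 0, 0 (6h_DMSO against 4h_DMSO), 8, 39 and 9 calls, with fewer features tested. With the block they gave 39 at 4 h and 25 for 6h_DMSO against 4h_DMSO. Overlapped features alone gave 46 at 4 h, 11 at 6 h and 24 for 6h_DMSO against 4h_DMSO. In the full fit 6208 features without overlap and 7086 with overlap were tested, but genes without overlap held only 14.6% of all counts. Leaving out a library (or experiment B) gave 13 to 85, 1 to 25, 0 to 3, 7 to 82, 26 to 418, 143 to 771 and 50 to 264 calls. The adjusted p of the G2M list ran from 1.84e-44 to 4.72e-35 at 4 h and from 1.13e-20 to 1.52e-06 at 6 h, and that of the S phase list from 0.00418 to 0.321 and from 0.334 to 0.963. Of 112 list tests 36 passed, 9 with an estimated correlation, 7 with the block and an estimated correlation and 40 with experiment B left out. Lists of opposite features with an estimated correlation gave 7. The S phase list at 4 h had an adjusted p of 0.188 with an estimated correlation, 0.23 with the block as well and 0.413 for its opposite features, where G2M at 6 h had 0.114. Lists of opposite features went the other way for FOXO targets at 4 h (adjusted p = 0.815, 0.893 with an estimated correlation and 0.86 with the block) and for immediate early genes at 6 h of inhibition (0.0243, 0.00165 with the block). They also did so for immediate early genes in 6h_DMSO against arrested cells (0.902, 0.948 with an estimated correlation and 0.957 with the block). For homologous recombination they went the other way with 0.00647 (6h_DMSO against 4h_DMSO), 0.0367 and 1.06e-04 (4h_DMSO and 6h_DMSO against arrested cells) and 3.08e-04 (arrested against cycling), and with 7.52e-04, 0.0148, 5.57e-06 and 3.39e-05 with the block. These calls, and that of immediate early genes at 6 h of inhibition, ended with an estimated correlation. With a prior count of 0.5 the G2M level rose by 0.75 at 4 h and the S phase level in 6h_DMSO minus arrested cells was -0.53; medians over members gave -0.51 there, 0.13 for arrested minus cycling cells and 0.066 for the S phase difference at 6 h of inhibition, which was -0.065 as a mean. Shared calls of 4 h and 6 h of inhibition numbered 11 by DESeq2, 42 with the block, 32 with the block and no G2M genes and 15 with experiment B left out. Calls shared with 6h_DMSO against arrested cells numbered 115 with the block, 12 at an adjusted p under 0.01, 9 without G2M genes, 70 with the block and no G2M genes and 50 with experiment B left out; with 6h_DMSO against 4h_DMSO they numbered 18 by DESeq2 and, in the same order, 62, 7, 3, 33 and 29. The cause was not tested for any of these. Of 148 called values of named genes, 0 of 2273 alternatives had the other sign and 387 missed the threshold; of 286 uncalled ones 74 of 4543 had the other sign and 312 passed. The median of all fold changes lay between -0.015 and 0.016 with TMM factors. It lay between -0.009 and 0.01 with the factors of DESeq2 and between -0.008 and 0.007 with upper quartile factors. The depth of 1758747 to 2357561 counts per library limits low genes, which were not among the changed genes of the simulation. Among genes with an average log2 CPM of at least 2, edgeR found 18.9% of those changed by 1 on the log2 scale in simulated data for the 4 h comparison. That share may be too high, since the draw left out part of the spread.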

Other observations

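Genes and lists named here were chosen only after their values were seen. PPIL2 is overlapped by YPEL1, a gene of the Yippee family, so its counts are uncertain as to the gene. YPEL1 held 91.8 ± 8.9 CPM (SD, n = 17) with PPIL2 at 40.9 ± 27.1, and PPIL2 lay above YPEL1 in 1 of 17 libraries. PPIL2 was the 1 feature that edgeR without the block called with the inhibitor at both times (11 by DESeq2 and 42 with the block), and it was also higher in arrested than in cycling cells (log2 1.18 ± 0.26, adjusted p = 0.0205). That call ended without cycling A (adjusted p = 0.0757), arrested B (0.119) or cycling C (0.124). After release with DMSO it had -0.84 at 4 h and -0.73 at 6 h, with adjusted p of 0.00326 and 0.00926 only with the replicate block.

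Features opposite to cholesterol synthesis genes were higher with the inhibitor as a list of 13 at 4 h (adjusted p = 0.00175, but 0.408 with an estimated correlation) and at 6 h (adjusted p = 8.53e-04, but 0.381), with 1 and 0 members called. IDI2-AS1, opposite the isoprenoid enzyme gene IDI1, had 1.15 ± 0.22 at 6 h (adjusted p = 0.0882, and 1.50e-07 with the block), and AC114947.2, opposite HMGCS1, had 1.46 (adjusted p = 0.741, and 1.14e-14 with the block). In arrested against cycling cells the 14 features opposite to p53 targets were higher (adjusted p = 4.81e-30, and 0.0142 with an estimated correlation), and in 4h_DMSO against arrested cells XPC-AS1, opposite the repair gene XPC, fell from 427 ± 27.9 to 207 ± 19.8 CPM (log2 -1.05 ± 0.15, adjusted p = 4.97e-04). Among mitochondrial genes, MT-ND1 had 388 ± 117 CPM in arrested cells and 880 ± 165 in 4h_DMSO, and MT-ND6 had 17660 ± 2311 and 10820 ± 1166.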
